A study of Mus musculus with 10 samples.

How the data were processed

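Total RNA of mouse osteoblasts, the bone-forming cells, was measured on 10 Affymetrix arrays with 45101 probe sets. The mice were 2 to 3 days old. Per the labels, 4 samples were wild type, 3 carried osteoblast-specific constitutively expressed β-catenin (called β-catenin active here) and 3 had FoxO1 deleted in osteoblasts. Sex is recorded as undetermined. The series' design counts mice, and the labels do not say whether a sample came from 1 animal, a pool or a culture, so p-values measure only the spread between these samples, which may be technical.

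The deposited table holds log2 MAS5 signal, MAS5 being named without a version in the submitters' processing notes. The base follows from the values, which run from -3.86 to 15.86. Taken as log2, the mean of the linear values after trimming 2% at each end was 499.994 in wild type 1 and 500.013 in wild type 3, and near 500 in each other array. That equality is the per-array scaling visible in the deposited log2 signal, and no further step between arrays is given in the sources used here. Biotin-labelled cRNA came from 500 ng of total RNA, per the labels. Low values were not floored, and the number of arrays limits the precision.

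Probe sets were named from the platform annotation paired with the table. Of the 45101 probe sets, 34958 had 1 gene, 932 several and 9211 none listed. The gene ID of 99.4% of the 1-gene probe sets was found in the RefSeq table of assembly GRCm38.p6. That table served only for names and for which genes neighbour each other, since no genome build is given for the array, and no coordinates are printed. A probe set was kept if the third-highest of its 10 values lay above the table's median of 7.15, which left 20127 probe sets with 1 gene. Each of the 11357 genes tested was represented by its kept probe set with the highest mean over the 10 arrays. Among 33 other kept probe sets of named genes that passed the test, 2 had the opposite sign.

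Expression was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per genotype, all 10 arrays in 1 fit and no covariates. The 3 pairs of genotypes were compared with eBayes with a mean-variance trend, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. This leaves 7 residual degrees of freedom. Values per genotype are mean ± SD on the log2 scale, with n = 4 for wild type and n = 3 for each other genotype. Wild type 1 and 2, and wild type 3 and 4, form pairs of closely similar arrays, so the wild-type SD and the SE may rest on 2 independent units. Log2 differences are given ± SE. A fold is 2 to the power of the log2 difference.

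A further test used 20 gene lists. They cover Wnt targets and feedback, the Notch pathway, FoxO targets, osteoblast differentiation and bone matrix, secreted regulators of osteoclasts and blood cells, ER stress and amino acid response, interferon response, immediate early and heat shock genes, and the cell cycle. Marker lists cover leukocytes and macrophages, osteoclasts, erythroid cells, endothelial cells, skeletal muscle, chondrocytes, adipocytes, keratinocytes, neural cells, and fibroblasts and smooth muscle, with sex-linked genes as the last. Osteoblast samples can themselves express many of the fibroblast, chondrocyte and secreted-factor genes. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 60 tests. Camera with an estimated correlation and fry stood beside it. Of the lists that passed camera, fry passed only Wnt targets and endothelial markers, where its adjusted p is given. A list's score in an array is the mean deviation of its genes from their means over all arrays.

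The groups, the filter, the fit, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule takes Ctnnb1, Foxo1, Jag1, Axin2, Col1a1 and Bglap, for which no probe set is listed in the annotation used here. It adds the 8 largest rises and 8 largest falls that pass the test without overlap between arrays, or the 5 smallest p-values in a direction where fewer than 5 genes pass. It also takes up to 4 members of each list that pass, or the 2 with the smallest p, and the genes changed in both genotypes. Other genes named beside a list, such as Dkk1, Cxcl12, Rrm2 and Matn1, were chosen after their values were seen.

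These other settings were 2 other filters, quantile and median scaling, 2 other ways to represent a gene, fitting only the groups compared, the replicate number as a block, array weights, 2 other variance priors, split controls and leaving out each array. Settings added after the data were seen were 16 added on the linear scale, a term for Xist signal, arrays with low or with high Xist signal alone, no sex chromosomes, no genes within 20 Mb of Foxo1, and each pair of similar wild-type arrays averaged to 1 unit, which leaves 5 residual degrees of freedom.

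The fit was tested on simulated data over the 11357 genes in 10 simulations. For β-catenin active against wild type it recovered 39.4% of changes of 0.5, 83.1% of changes of 1 and 98.2% of changes of 2 on the log2 scale, with 4.61% false among the called genes. For FoxO1 deleted against wild type it recovered 35.2%, 81.8% and 97.6%, with 4.10% false. For β-catenin active against FoxO1 deleted it recovered 29.9%, 78.5% and 98.2%, with 6.40% false. Camera called a shifted list in 10 of 10 simulations and 0 other lists. These simulations draw samples that differ only by random noise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.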

Results

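Gene expression was measured in osteoblasts of 4 wild-type samples, 3 with active β-catenin and 3 with FoxO1 deleted. β-catenin, encoded by Ctnnb1, carries canonical Wnt signals to the nucleus, and FoxO1 is a transcription factor of stress and metabolic responses. Array medians lay between 7.02 and 7.22 on the log2 scale. The mean correlation of an array with the others of its genotype was 0.978 ± 0.000522 in wild type, 0.969 ± 0.00495 with active β-catenin and 0.960 ± 0.00412 with FoxO1 deleted. Both differences from wild type had a permutation p of 0.0286, the smallest this design allows, and 0.214 after adjustment over the quality tests. The permutation shuffled these values without computing them anew for the regrouped arrays. Each value is built from the other arrays of its genotype, so the values are not independent and this p cannot decide whether the genotypes differ. The wild-type value hides a structure. Wild type 1 and 2, and wild type 3 and 4, correlated at 0.990 and 0.989, and arrays from different pairs at 0.971 to 0.973, below the 0.979 of β-catenin active 2 and 3. Whether the members of a pair share a source is not stated, so 4 wild-type arrays may be fewer independent samples, and these p-values count them as 4. The Actb 3' minus 5' signal, a measure of RNA integrity, was 0.69 ± 0.07 in wild type, 0.87 ± 0.02 with active β-catenin and 0.87 ± 0.11 with FoxO1 deleted, each against wild type at an exact permutation p of 0.0571 (adjusted 0.214). Every wild-type array was at 0.77 or less and every other array at 0.80 or more. By this measure RNA integrity runs with both differences from wild type, and it was weighed later only for the cell cycle list.

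Transcripts known from other cell types were measured above the table's median. Wild-type means were 14.64 for Acta1 and 12.42 for Myh3 of skeletal muscle, 13.86 for Mmp9 of osteoclasts and 13.33 for Csf1r of macrophages. Levels of different probe sets are not comparable, so these values give no share of any cell type. Xist, expressed from the inactive X chromosome, was at 14.25 and 14.05 in wild type 3 and 4, and at 14.22 and 14.43 in FoxO1 deleted 2 and 3. It was at 8.96 or less in the other 6 arrays, among them all 3 with active β-catenin. Eif2s3y on the Y chromosome was at 4.34 or less in the 4 arrays with high Xist and at 10.78 or more in the other 6.

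The targeted genes come first. Ctnnb1 stood at 14.48 ± 0.09 in wild type and 14.45 ± 0.04 with active β-catenin (adjusted p = 0.941). Its 2 other kept probe sets differed by -0.28 (adjusted p = 0.534) and -0.34 (adjusted p = 0.104). Foxo1 stood at 10.04 ± 0.07 in wild type and 9.87 ± 0.24 with FoxO1 deleted, a log2 difference of -0.17 ± 0.11 (adjusted p = 0.706), and its 2 other kept probe sets differed by 0.05 and 0.10. Which part of either gene was altered is not given in the sources used here. A probe set outside the altered part checks nothing, so these values neither bear out nor contradict the genotype labels.

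The first comparison asks what active β-catenin does to osteoblast expression. Among Wnt feedback genes, Notum, a secreted enzyme that inactivates Wnt proteins, rose 3.03-fold from 7.81 ± 0.24 to 9.41 ± 0.20. Both secreted partners that set osteoclast formation rose, Tnfrsf11b (osteoprotegerin, the decoy receptor) 3.29-fold and Tnfsf11 (RANKL, the osteoclast-inducing ligand) 2.61-fold. Hey1, a Notch target, rose 2.89-fold, and Cdkn1a, a cell cycle inhibitor, rose 1.90-fold. The largest rise was that of Coch, a secreted extracellular matrix protein, 28.9-fold from 5.70 ± 0.52 to 10.55 ± 0.56.

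In all, 89 of 11357 genes changed, 68 higher and 21 lower, and 35 of the rises and 5 of the falls were at least 2-fold. The arrays of the genotypes did not overlap for any of the 89. Over all genes 1594 did not overlap (14.04%), where chance gives 5.71%, and 1373 genes had an unadjusted p under 0.05 where 567.85 are due by chance. These chance values take the wild-type arrays as independent samples. If the members of a similar pair are not independent, chance gives more genes without overlap. With each such pair averaged to 1 unit, 705 genes had an unadjusted p under 0.05 in limma. Besides Coch, the largest rises were those of Car12, a carbonic anhydrase (7.43-fold), Sp6, a transcription factor (6.58-fold), Ptgs2, the prostaglandin-forming cyclooxygenase (5.77-fold), Irx6 (4.67-fold), Ism1 (3.56-fold), Gchfr (3.36-fold) and Cyp1b1 (3.33-fold). Except for Cyp1b1, the wild-type means of these genes and of Coch lie under the table's median of 7.15, so their folds and their order are inexact. The largest falls were those of Olfm4 (-2.76 on the log2 scale), Lcn2 (-2.71) and Ifitm6 (-2.14), followed by Rtel1 (-1.63), Pde1a (-1.42), Mycbp (-0.78), Tent5a (-0.76) and Mlip (-0.68). Olfm4 and Lcn2 are known from neutrophils, and erythroid markers were lower in the same arrays (adjusted p = 0.397 with an estimated correlation). Every array with FoxO1 deleted also lay below every wild-type array for Olfm4 (8.65 or less against 9.03 or more), Lcn2 (8.51 against 9.11) and Ifitm6 (7.72 against 8). These falls are therefore not particular to active β-catenin. With active β-catenin all arrays lay under the table's median for these genes, so the sizes are inexact. The Rtel1 call rests on 1 probe set, since its 2 others differed by 0.20 and -0.01. The 3 others of Mycbp differed by -0.24, -0.48 and -0.21, less than the one used.

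The count depended on the arrays. It was 31 without wild type 1, 32 without wild type 2, 45 without wild type 3, 35 without wild type 4, 40 without β-catenin active 1 and 40 without β-catenin active 3. The calls of Coch, Car12, Sp6, Irx6, Cyp1b1, Notum and Cdkn1a held whichever array was left out. Ism1 was lost without β-catenin active 1 (highest adjusted p 0.0520) and Hey1 without wild type 3 or 4 or β-catenin active 1 or 3 (0.0826). Tnfrsf11b was lost without wild type 1, 2 or 3 or β-catenin active 1 or 2 (0.106), and Lef1 without any 1 of the 7 arrays compared (0.142). Tnfsf11 was lost without any of the 10 arrays except FoxO1 deleted 3 (0.163). Its signal was 10.04 in wild type 1 and 2 and at 9.12 or less in wild type 3 and 4, and in arrays with low Xist signal alone its difference was 0.90 in place of 1.38 (adjusted p = 0.0862). Ptgs2 was lost without wild type 1, 2 or 4 or any array with active β-catenin (0.106), and Gchfr without any wild-type array or β-catenin active 1 or 3 (0.121). Among the falls, Olfm4 was lost without any 1 of the 7 arrays compared (0.146), and Lcn2 without wild type 1, 2 or 4 or any array with active β-catenin (0.0779). Ifitm6 was lost without wild type 1 or 2 or β-catenin active 1 or 3 (0.0826), Rtel1 without any wild-type array or β-catenin active 2 or 3 (0.102), and Pde1a without any wild-type array or β-catenin active 3 (0.107). Mycbp was lost without wild type 1, 2 or 4 or β-catenin active 1 or 3 (0.123). Tent5a (0.0667) and Mlip (0.0988) were lost without wild type 1, 2 or 3 or β-catenin active 2 or 3. With each pair of similar wild-type arrays averaged to 1 unit, the differences were the same but only 9 of the 89 genes passed, all higher. Coch, Car12, Sp6, Notum and Cdkn1a were among them (highest adjusted p 0.0297), and Irx6 (0.0518), Tnfrsf11b (0.202), Lef1 (0.233), Hey1 (0.187), Tnfsf11 (0.225) and each of the 8 falls were not. With a term for Xist signal 35 genes passed, and 32 of them were among the 89.

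**Figure D1:**
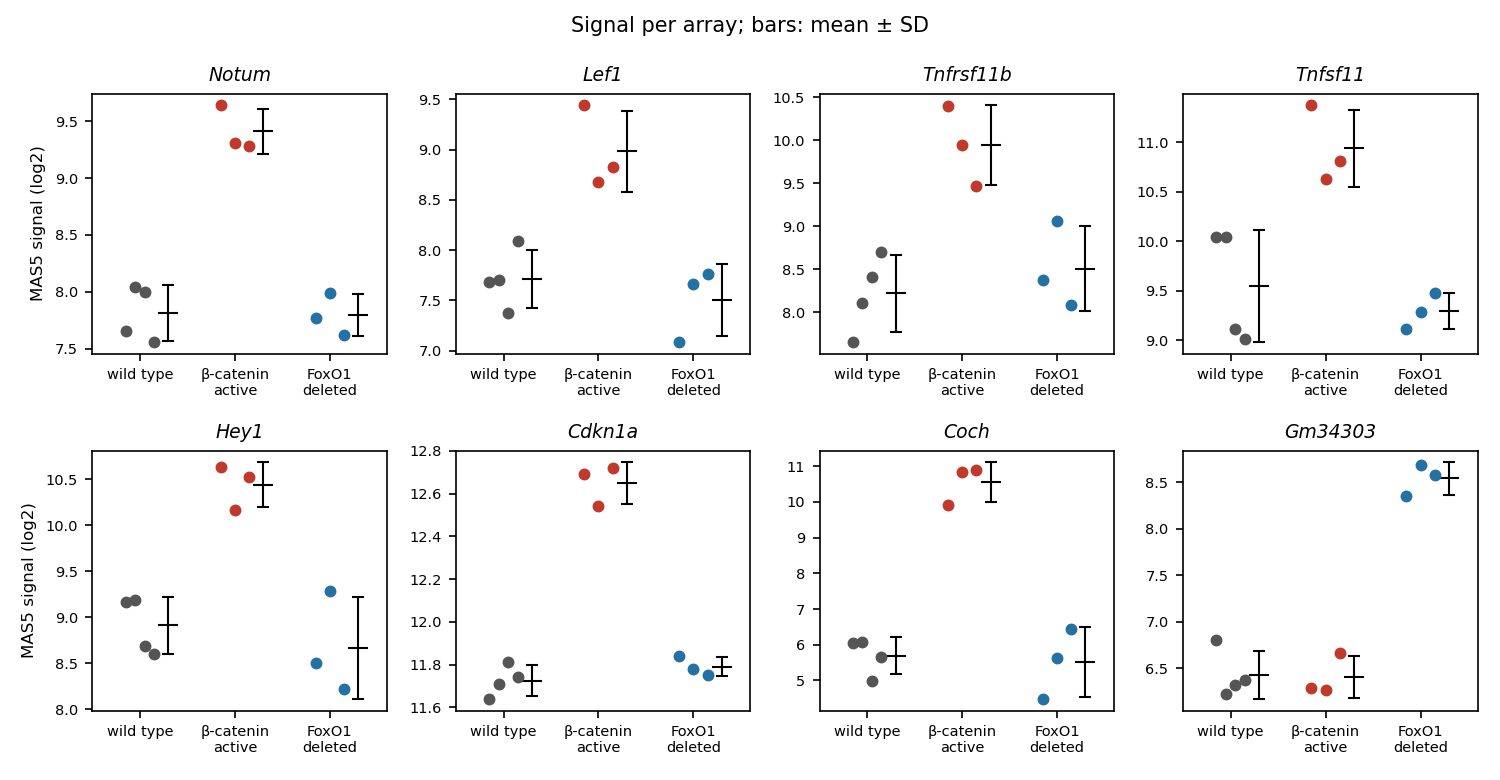
MAS5 signal (log2) of 8 genes, one point per array, with the mean ± SD of each genotype to the right of its points. Notum lay between 9.28 and 9.64 with active β-catenin and at 8.04 or less in all other arrays, and Gm34303 lay between 8.35 and 8.69 with FoxO1 deleted and at 6.81 or less in all other arrays.

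Of the 19 measured Wnt targets and feedback genes, 3 rose and 16 did not pass the test. Besides Notum and Tnfrsf11b, Lef1, a transcription factor that binds β-catenin, rose 2.41-fold (adjusted p = 0.0359). Axin2, a common Wnt readout, differed by 0.26 ± 0.14 (adjusted p = 0.515). Adjusted over the list alone, 7 genes were higher and 1, Dkk1, was lower (log2 difference -0.69). The list as a whole was higher, with 17 of 19 genes positive and a mean difference of 0.44 (camera adjusted p = 2.9e-07; adjusted p = 0.0843 with an estimated correlation; fry adjusted p = 0.00648). All 3 arrays with active β-catenin scored above all others.

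Of 17 Notch pathway genes, Hey1 rose and 16 did not pass. Jag1, a Notch ligand, differed by 0.29 ± 0.15 (1.22-fold, adjusted p = 0.503). The list was higher by 0.26 on average (camera adjusted p = 0.00423; adjusted p = 0.448 with an estimated correlation), with 4 genes higher when adjusted over the list alone. Without β-catenin active 1 the mean was 0.19 and the adjusted p 0.0520. Of 14 secreted regulators of osteoclasts and blood cells, Tnfrsf11b and Tnfsf11 rose (camera adjusted p = 0.0490; adjusted p = 0.448 with an estimated correlation). Adjusted over the list alone, 5 were higher and 1, Cxcl12, was lower (log2 difference -0.35). The secreted list's call was lost without wild type 1, β-catenin active 1 or 2, or FoxO1 deleted 1, with a highest adjusted p of 0.195.

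Of 23 FoxO targets, Cdkn1a alone rose (adjusted p = 4.4e-04), and the list as a whole did not pass (mean 0.12, camera adjusted p = 0.129; 2 higher when adjusted over the list alone). Among 18 osteoblast and bone matrix genes 0 passed limma's test over all genes, and 3 passed when adjusted over the list alone. These were Sost (0.96, adjusted p over all genes 0.0637), Phex (0.54, 0.0889) and Mepe (-2.35, 0.152), all made by osteocytes. Mepe was at 7.96 in β-catenin active 1. It was at 4.15 and 6.37 in β-catenin active 2 and 3, under the table's median, so its size is inexact. The other kept probe set of Phex differed by 0.14. Col1a1 differed by 0.08 ± 0.08. The list's mean was -0.02 and its median 0.09 (camera adjusted p = 0.245, in the upward direction). Psat1, an enzyme of serine synthesis, was the only one of 14 ER stress and amino acid response genes to change (-0.55, adjusted p = 0.0276), and the list did not pass (camera adjusted p = 0.406). Psat1 lost its call without any 1 of the 7 arrays compared (highest adjusted p 0.115), and its other kept probe set differed by -0.24.

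All 24 cell cycle genes had a negative difference, and 0 passed limma's test over all genes. The largest were Rrm2 (-0.53) and Mcm3 (-0.47, adjusted p = 0.0968), and adjusted over the list alone Mcm3 was lower. The list's mean was -0.31 (camera adjusted p = 2.25e-08; adjusted p = 0.451 with an estimated correlation). Without β-catenin active 1, which had the lowest score of all arrays (-0.49), the mean was -0.13 (adjusted p = 0.00703). Erythroid markers were lower in the same arrays, by a mean of -2.22 over 4 genes (camera adjusted p = 1.1e-04; adjusted p = 0.397 with an estimated correlation). All 4, among them Klf1 (-2.98) and Slc4a1 (-2.07), were lower when adjusted over the list alone. Klf1 and Rhag were at 6.02 or less in every array with active β-catenin, under the table's median, so the mean of -2.22 is inexact.

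Several marker lists moved with the genotype. Endothelial markers were higher by 0.26 (camera adjusted p = 4.1e-04; adjusted p = 0.0843 with an estimated correlation; fry adjusted p = 0.00420), with 7 of 12 higher when adjusted over the list alone. Chondrocyte markers were higher by 0.50 (camera adjusted p = 6.05e-04; adjusted p = 0.597 with an estimated correlation), led by Sox9 (0.87, adjusted p = 0.0838). Fibroblast and smooth muscle markers were higher by 0.26 (camera adjusted p = 0.00219; adjusted p = 0.448 with an estimated correlation), and by 0.17 without wild type 1 (adjusted p = 0.0295), and 2 of 14 rose, Thy1 1.88-fold and S100a4 1.34-fold. Thy1 lost its call without any 1 of the 7 arrays compared (0.123), and S100a4 without any wild-type array, β-catenin active 1 or 3 or FoxO1 deleted 1 (0.145). Osteoclast markers were lower by a mean of -0.26 (camera adjusted p = 0.0490; adjusted p = 0.640 with an estimated correlation). The mean was -0.16 without wild type 1 and -0.15 without wild type 2, and the call was lost without these or β-catenin active 2 or 3, with a highest adjusted p of 0.254. The remaining lists did not pass in this comparison, with camera adjusted p = 0.545 for interferon response, 0.0873 for immediate early and heat shock genes, 0.346 for leukocytes and macrophages, 0.215 for skeletal muscle, 0.162 for adipocytes, 0.971 for the 1 keratinocyte gene measured (Krt10), 0.316 for neural cells and 0.451 for sex-linked genes.

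**Figure D2:**
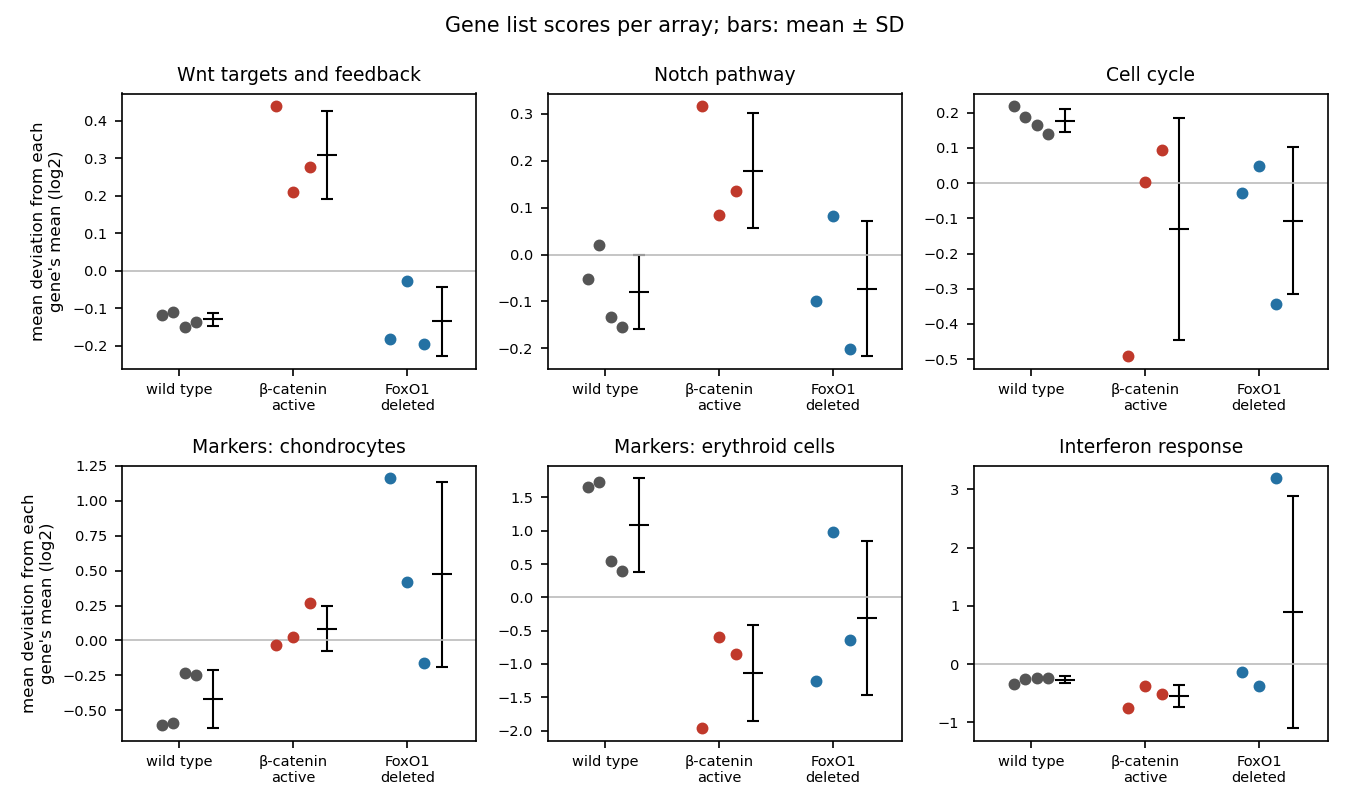
Mean deviation of the genes of 6 lists from each gene's mean over all arrays (log2), one point per array, with the mean ± SD of each genotype to the right of its points. The Wnt score separates the 3 arrays with active β-catenin from all others, and the interferon score of FoxO1 deleted 3 is 3.19.

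The second comparison asks what loss of FoxO1 does. Gm34303, an annotated transcript directly beside Foxo1 on its chromosome, rose from 6.43 ± 0.26, under the table's median, to 8.54 ± 0.17, about 4.31-fold (adjusted p = 0.00873). Alad, an enzyme of heme synthesis, fell by 0.92 on the log2 scale (adjusted p = 0.00873), and Exosc9, a subunit of the RNA exosome, fell by 0.84 (adjusted p = 0.0227). Chondrocyte markers were higher as a group, and cell cycle genes and erythroid markers were lower (adjusted p = 0.397, 0.451 and 0.448 with an estimated correlation).

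These 3 genes, 1 higher and 2 lower, were the only ones of 11357 to change, while 889 had an unadjusted p under 0.05 where 567.85 are due by chance. Over all genes 9.03% did not overlap, where chance gives 5.71%. Both chance values take the wild-type arrays as independent samples. The count was 0 without FoxO1 deleted 1 and 0 without FoxO1 deleted 3 (1043 and 799 genes at an unadjusted p under 0.05 in limma), 7 without FoxO1 deleted 2 and 1 without wild type 1. Gm34303 kept its call except without FoxO1 deleted 1 or 3, where its adjusted p was at most 0.0582. Alad lost its call without these or wild type 1 (0.0582), and Exosc9 without these, β-catenin active 3 or any 1 of the wild-type arrays (0.112). With each pair of similar wild-type arrays averaged, 0 genes passed in limma (345 at an unadjusted p under 0.05), and the adjusted p was 0.159 for Gm34303, 0.219 for Alad and 0.360 for Exosc9. That count of 345 lies under the 567.85 due by chance. The genes next in line did not pass. They were Rbfa (0.57, adjusted p = 0.117), Dcaf17 (0.71, 0.117), Arhgap39 (2.45-fold, 0.340) and Crispld2 (0.52, 0.340) among the higher, and Spata5 (-0.97, 0.0535), Gjb6 (-1.37, 0.117) and Pgghg (-0.81, 0.324) among the lower.

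Of 14 chondrocyte markers 0 passed limma's test over all genes and 11 were higher when adjusted over the list alone. They include Ucma (1.69), Matn1 (1.43), Col9a3 (1.41) and Col2a1 (1.16). The list's mean was 0.89 (camera adjusted p = 2.1e-11; adjusted p = 0.397 with an estimated correlation). FoxO1 deleted 1 scored 1.16, FoxO1 deleted 2 scored 0.42 and FoxO1 deleted 3 scored -0.16, and leaving out 1 array gave means between 0.55, without FoxO1 deleted 1, and 1.21. The mean was 1.76 in arrays with low Xist signal and 0.37 in those with high Xist signal. FoxO1 deleted 1 is the only FoxO1 array with low Xist signal, so the first value rests on it alone. All 24 cell cycle genes were negative again, with a mean of -0.28 (camera adjusted p = 2.25e-08; adjusted p = 0.451 with an estimated correlation), Ccna2 at -0.63 and Mcm6 at -0.35, and 0 passed over all genes or over the list alone. Without FoxO1 deleted 3 the mean was -0.17 (adjusted p = 3.3e-04). The 4 erythroid markers had a mean of -1.39 (camera adjusted p = 0.00209; adjusted p = 0.448 with an estimated correlation), 3 of them lower when adjusted over the list alone. Klf1 and Rhag were at 5.92 or less in FoxO1 deleted 1 and 3, under the table's median, so this size is inexact. Leaving out 1 array gave means between -2.03 and -0.91, the last without FoxO1 deleted 1 (adjusted p = 0.0433). FoxO1 deleted 2 scored 0.98, inside the wild-type range of 0.39 to 1.72. In arrays with low Xist signal the mean was -2.95, again from FoxO1 deleted 1 alone, and in those with high Xist signal it was -0.30 (adjusted p = 0.332).

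Interferon response genes were higher by 1.16 (camera adjusted p = 0.0146; adjusted p = 0.597 with an estimated correlation), and this came from 1 array. FoxO1 deleted 3 scored 3.19, and without it the mean was 0.02 (adjusted p = 0.605), while without FoxO1 deleted 2 it was 1.80. Neural markers were lower, with Tubb3 at -1.55 and Stmn2 at -1.36, both lower when adjusted over the list alone. Their mean was -0.97 (camera adjusted p = 0.0146; adjusted p = 0.448 with an estimated correlation), and without FoxO1 deleted 2 it was -0.58 (adjusted p = 0.129). Osteoclast markers were lower by a mean of -0.27 (camera adjusted p = 0.0198; adjusted p = 0.597 with an estimated correlation). That call was lost without wild type 1 (-0.17), wild type 2 (-0.16) or FoxO1 deleted 1, the last giving -0.05 (adjusted p = 0.840). The direction was not stable, since among arrays with high Xist signal, a setting chosen after the data were seen, the mean was 0.26 (adjusted p = 0.00127). Osteoblast and bone matrix genes were higher by 0.12 (camera adjusted p = 0.0497; adjusted p = 0.597 with an estimated correlation), with Dmp1 at 0.33 and 0 passing over the list alone. That call was lost without wild type 1, 3 or 4, β-catenin active 3 or FoxO1 deleted 2 or 3, with a highest adjusted p of 0.312, and the mean was 0.19 without FoxO1 deleted 1 and 0.08 without FoxO1 deleted 3.

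FoxO targets did not differ as a group (mean 0.03, camera adjusted p = 0.972), and 0 of 23 passed over all genes or over the list alone. Neither Wnt targets (mean -0.01, 0.741) nor Notch genes (mean 0.01, 0.787) passed. Axin2 was at -0.46 ± 0.14 (adjusted p = 0.488) and Jag1 at 0.22 ± 0.15 (adjusted p = 0.754). Among leukocyte and macrophage markers Itgam was lower when adjusted over the list alone (-1.01), and the list did not pass (camera adjusted p = 0.545).

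The third comparison tests directly whether the genotypes differ. Coch was 32.6-fold, Car12 6.62-fold, Sp6 5.43-fold and Irx6 5.30-fold higher with active β-catenin than with FoxO1 deleted. Of the 8 largest rises in the first comparison, 7 also passed here, and Ptgs2 did not (log2 difference 1.54, adjusted p = 0.282). Those 8 genes were picked for high values in the same arrays with active β-catenin, and both comparisons share 1 fit. Passing again is therefore no independent support. The folds of Coch, Car12, Sp6 and Irx6 too are inexact, since their means with FoxO1 deleted lie under the table's median. Notum (3.07-fold), Lef1 (2.79-fold), Nkd1 (1.82-fold), Hey1 (3.42-fold), Tnfsf11 (3.12-fold) and Cdkn1a (1.82-fold) were higher too. Tnfrsf11b did not pass here (1.43, adjusted p = 0.103), nor did Axin2 (0.72, adjusted p = 0.0741). The Nkd1 call rests on 1 probe set, since its 2 others differed by 0.32 and 0.40, and so does that of Ism1, whose other differed by 0.74. Wfdc18 was 61.7-fold higher, from 3.04 ± 1.40 to 8.99 ± 0.31, where the lower mean lies far under the table's median. Gm34303 (-2.13), Mt1 (-1.03), Mst1r (-0.91) and Ctsh (-0.77) were lower with active β-catenin. The other kept probe set of Mt1 differed by -0.35, so that call also rests on 1 probe set.

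In all, 76 genes differed, 66 higher and 10 lower with active β-catenin, and all 76 showed no overlap between arrays. Over all genes 9.54% did not overlap, where chance gives 10%, and 912 genes had an unadjusted p under 0.05. Other leading genes were Fabp7 (8.06-fold), Adra2c (4.64-fold), Gchfr (4.11-fold) and S100a4 (1.36-fold), and Tent5a (-0.76), D430019H16Rik (-0.70), Col22a1 (-0.56) and Skp2 (-0.50) were lower. The size for Adra2c depends on the probe set, its other one differing by 4.07 on the log2 scale in place of 2.21. The count was 49 with the wild-type pairs averaged, 45 without β-catenin active 2, 30 without β-catenin active 3 and 29 without FoxO1 deleted 1. Coch, Fabp7, Car12, Sp6, Irx6, Gm34303, Notum and Cdkn1a kept their calls whichever array was left out. Hey1 was lost without β-catenin active 3 or FoxO1 deleted 1 (highest adjusted p 0.0662), Adra2c and Gchfr (0.0961) and Nkd1 (0.09995) without these or β-catenin active 1, and Lef1 without these 3 or FoxO1 deleted 2 (0.0891). Wfdc18 was lost without any array with active β-catenin or FoxO1 deleted 1 or 2 (0.124), and Tnfsf11 without any 1 of the 6 arrays compared (0.114). Mt1 was lost without any array with active β-catenin or FoxO1 deleted 2 or 3 (0.0851), Ctsh without β-catenin active 2 or 3 or any array with FoxO1 deleted (0.103), and Tent5a without β-catenin active 2 or 3 or FoxO1 deleted 2 or 3 (0.0875). D430019H16Rik was lost without any array but wild type 2 or 3 or FoxO1 deleted 2 (0.115), Col22a1 without any but β-catenin active 1 (0.162), Skp2 without any but FoxO1 deleted 3 (0.174), S100a4 without any but β-catenin active 2 (0.181) and Mst1r without any 1 of the 10 (0.202).

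As a list, Wnt targets were higher with active β-catenin than with FoxO1 deleted by 0.44 (camera adjusted p = 6.8e-08; adjusted p = 0.0843 with an estimated correlation; fry adjusted p = 0.00648) with 8 of 19 higher when adjusted over the list alone. Notch genes were higher by 0.25 (0.00480; adjusted p = 0.448 with an estimated correlation) and endothelial markers by 0.17 (0.0118; adjusted p = 0.248 with an estimated correlation; fry adjusted p = 0.0189). Without β-catenin active 1 the adjusted p of the Notch and endothelial lists was 0.104 and 0.0800. Chondrocyte markers were lower by a mean of -0.39 (0.00423; adjusted p = 0.597 with an estimated correlation), with an adjusted p of 0.0517 without β-catenin active 1, -0.04 without FoxO1 deleted 1 (adjusted p = 0.767) and -0.71 without FoxO1 deleted 3. Interferon genes were lower by a mean of -1.44 (0.00294; adjusted p = 0.451 with an estimated correlation), and -0.29 without FoxO1 deleted 3 (adjusted p = 0.224).

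Finally the changes in both genotypes against wild type were compared. Alad, lower with active β-catenin (-0.60, adjusted p = 0.0207) and with FoxO1 deleted (-0.92, adjusted p = 0.00873), was the 1 gene that passed in both, where independent lists of these sizes would share 0.00370 genes in that direction. That value ignores that both lists use the same wild-type arrays. With these split 2 and 2 between the comparisons, 0.17 genes were shared on average over the 6 assignments. This was 1 gene, with wild type 3 and 4 as the controls of active β-catenin. Where members of a similar pair fell on both sides, the controls may not be separate. The call of Alad with active β-catenin was lost without wild type 1, 2 or 4 or any array with active β-catenin (highest adjusted p 0.0854). The number of genes passing in both was 0 without wild type 1, 2 or 4, any array with active β-catenin, or FoxO1 deleted 1 or 3, and 4 without FoxO1 deleted 2. Across genes, which are not independent replicates, the log2 differences correlated at Pearson r = 0.465 and Spearman rho = 0.486. Unchanged simulated groups set against the same wild-type arrays gave means of 0.426 (0.389 to 0.461) and 0.395 (0.374 to 0.411). Shared controls alone thus give a high correlation, and both observed values lie above the simulated ranges. The simulated arrays vary independently, while the real wild-type arrays form similar pairs. A value above the simulated ones therefore does not show an effect shared by the genotypes. The covariance was 0.0379 against 0.0169 (0.0156 to 0.0191) simulated. With the wild-type arrays split 2 and 2 over the 6 possible assignments, r averaged 0.249 (-0.00127 to 0.352) and the covariance 0.0224. The assignments that kept both similar wild-type pairs whole gave r = 0.116 and -0.00127, with covariances of 0.0121 and -0.000151. Those that put 1 member of each pair on each side gave r from 0.339 to 0.352. If the members of a pair share a source, only the first kind has separate controls.

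**Figure D3:**
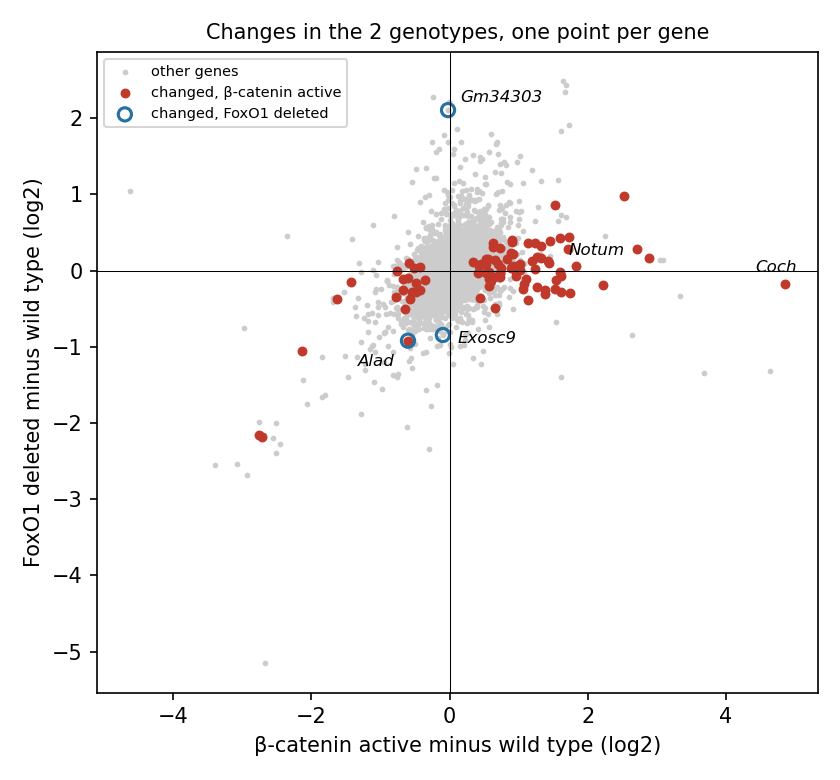
Log2 difference from wild type with active β-catenin (x axis) and with FoxO1 deleted (y axis), one point per gene. Filled points are the 89 genes changed with active β-catenin and open circles the 3 changed with FoxO1 deleted, and Alad is both.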

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

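All tests of explanations and the counts over regrouped samples in this part were chosen only after the results were seen; the gene list and genotype tests they refer to were planned.

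The 89 genes changed with active β-catenin include Wnt feedback genes, yet 2 of the 35 ways to divide these 7 arrays into 3 and 4, the real one among them, gave as many genes, so chance cannot be excluded on the count alone, and averaging the similar pairs of wild-type arrays left 9 genes. The highest other count was 130, from wild type 1, wild type 2 and β-catenin active 1 against the rest, which points to a structure in the samples: it shares 0 genes with the 89, and its skeletal muscle markers differ by a mean of -1.09 with 9 of 15 passing. From the slope on Xist signal within genotypes, sex of the mice predicted a shift of 0.0089, against 1.11 observed. The 95% interval was -0.03 to 0.05, or -0.06 to 0.08 with the similar wild-type pairs averaged. The 89 genes were called in these data partly for a small spread within genotypes, which favours a small slope. Every array with active β-catenin has low Xist signal, so this test cannot exclude sex. The Xist term ended 57 of the calls, whose median change moved from 0.73 to 0.70 while their median SE rose from 0.12 to 0.14 and the residual degrees of freedom fell from 7 to 6. For the 68 rises, 31 had a lower bound above the upper quartile of the chondrocyte markers (0.75), short of most of them. These genes were picked for their rises, and a cell type may be missing from the lists. Other cell types in the samples thus cannot be excluded for any of the 68. For the 21 falls, fewer erythroid cells predicted -0.25 from the slope within genotypes, against -0.94 observed. The 95% interval was -0.42 to -0.08, or -0.51 to -0.0024 with the similar wild-type pairs averaged. The 21 genes too were called partly for a small spread within genotypes, so this test does not measure an erythroid share.

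With FoxO1 deleted, genes with an unadjusted p under 0.001 lay near Foxo1 more often than elsewhere. With Gm34303 counted among the others, 5 of 106 genes within 20 Mb of Foxo1 met it, Exosc9 and Spata5 among them. Of the 11234 others, 24 met it, Gm34303 included (one-sided Fisher's exact p = 6.45e-06). The highest count in 980 other windows was 2. A strain difference in the DNA around Foxo1, carried along with the altered allele, is a candidate explanation, and an effect of the deletion on its neighbours was not tested apart from it. A sequence variant under single probe sets cannot be told apart, because 4 other probe sets of 3 of these genes had a median signed change of -0.10 (-0.28 to 0.31) against 0.71 for the probe sets used, which is too few. The count of 3 changed genes itself was reached by 2 of 35 divisions of the arrays, the real one among them, the highest other being 5, so chance cannot be excluded for it, and 0 genes passed in limma with the similar wild-type pairs averaged (345 unadjusted).

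Cell cycle genes were lower in both genotypes, with all 4 wild-type scores (0.14 or more) above the 6 others (0.10 or less). Chance in the shared wild-type arrays cannot be told apart: the exact permutation p was 0.0333 for this list, picked because it moved, and 0.133 after adjustment over the 20 lists. Fewer erythroid cells would predict a shift of -0.24 (95% interval -0.59 to 0.11) and RNA quality, by the Actb 3' minus 5' signal, -0.18 (-0.63 to 0.27), against -0.30 observed, and these wide intervals leave both open. A direct effect of both genotypes on proliferation also stays open, as untested.

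Of the 141 genes, list scores and array quality measures tested for a wild-type sample far from the other 3, 5 met the criterion, where chance gives 7.05. They are Axin2 in wild type 2 (8.48), Aurkb in wild type 4 (8.81), Coro1a in wild type 4 (9.04), Ccna2 in wild type 1 (10.74) and Mcm6 in wild type 2 (10.98). The chance value takes the wild-type arrays as independent samples. Since they form similar pairs, a single far array is harder to find, and a count under chance shows nothing. The effects of the genotypes differed for 76 genes, for which the 10 possible splits are too few for a share under 0.05 (1 of 10, highest other 0, limma, with 912 genes at an unadjusted p under 0.05 in the real one). They also differed by a mean of 0.44 for Wnt targets, 0.25 for Notch genes, -1.44 for interferon genes, 0.17 for endothelial markers and -0.39 for chondrocyte markers. None of these lists passed with an estimated correlation (adjusted p from 0.0843 to 0.597). The interferon difference was -0.29 without FoxO1 deleted 3, and the chondrocyte difference -0.04 without FoxO1 deleted 1. Among 3642 kept probe sets with no single gene listed, 4 changed with FoxO1 deleted, 3 higher and 1 lower (287 at an unadjusted p under 0.05). Active β-catenin changed 0 of them by limma (340 unadjusted), and 0 differed between the genotypes (274 unadjusted).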

How the results depend on the processing

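Settings on Xist signal, the sex chromosomes, genes near Foxo1 and similar wild-type pairs, and 16 added on the linear scale, were chosen after the data were seen; the other settings were planned. The 89 genes with active β-catenin became 141 with only the groups compared in the fit, 149 with array weights, 35 with an Xist term and 175 in arrays with low Xist signal, and 31 to 130 when 1 array was left out. The 3 genes with FoxO1 deleted became 5 after quantile normalization, 1 with only the groups compared, 29 with array weights, 5 without a variance trend, 96 in arrays with low Xist signal (1 FoxO1 array, assumed to vary like the other groups), 0 in arrays with high Xist signal (limma, 972 unadjusted), 1 without genes within 20 Mb of Foxo1, and 0 to 7 when 1 array was left out. The 76 genes between genotypes became 25 with only the groups compared, 18 with an Xist term, 12 in arrays with low Xist signal, and 29 to 62 when 1 array was left out. The correlation of effects was 0.436 without a filter, 0.446 with the stricter filter, 0.535 with array weights, 0.509 with an Xist term, 0.686 in arrays with low Xist signal, 0.490 without sex chromosomes, 0.249 on average with split controls, and 0.332 to 0.532 when 1 array was left out. With split controls that kept the similar wild-type pairs whole, it was 0.116 and -0.00127. Genes changed in both numbered 2 after quantile normalization, 0 with only the groups compared, 6 with array weights, 64 in arrays with low Xist signal, 0.17 on average with split controls, and 0 to 4 when 1 array was left out. Fewer arrays or genes enter several of these fits; otherwise the cause was not tested. Filters, scaling, probe set choice and the robust prior moved the count of active β-catenin against wild type by at most 1.5 times.

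With each pair of similar wild-type arrays (1 and 2, 3 and 4) averaged, 9 genes passed with active β-catenin, 0 with FoxO1 deleted (limma, 345 unadjusted), 49 between genotypes and 0 in both. The differences are the same by construction, the median SE of the 89 genes was 0.16 in place of 0.13, and 5 residual degrees of freedom were left in place of 7.

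The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated between -0.29 and 0.29. With the replicate number as a block, 15 genes passed with active β-catenin, 0 with FoxO1 deleted (limma, 635 unadjusted) and 22 between genotypes, the correlation was 0.531 and 0 genes were shared.

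With FoxO1 deleted, osteoblast genes turned to -0.0528 (adjusted p = 0.764) in arrays with low Xist signal, over alternatives from 5.0e-04 to 0.764, and osteoclast markers to 0.26 (adjusted p = 0.00127, over 20 lists) in arrays with high Xist signal, over alternatives from 1.8e-17 to 0.840; the cause was not tested. No list kept its call with an estimated correlation. The planned amounts added before taking logs were not run, since the values are already log2, and low signal near background limits folds such as that of Wfdc18.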

Other observations

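The arrays also differed within genotypes, among other things in the scores of marker lists. Tissue content itself was not measured. Skeletal muscle markers scored -0.75 and -0.69 in wild type 1 and 2 against 0.46 and 0.40 in wild type 3 and 4, and ranged from -0.53 to 0.62 with active β-catenin and from -0.41 to 0.61 with FoxO1 deleted. Neural markers ran the other way in wild type, at 1.26 and 1.22 in replicates 1 and 2 and -0.62 and -0.23 in replicates 3 and 4. Erythroid markers scored 1.66 and 1.72 in wild type 1 and 2, and 0.55 and 0.39 in wild type 3 and 4. Wild type 1 and 2 are the wild-type arrays with low Xist signal, so within wild type these differences run with it. Each pair is also closely similar as a whole (r = 0.990 and 0.989, against 0.971 to 0.973 across pairs), so a shared source of the members of a pair is another possible reason that was not tested, and settings with low or high Xist signal alone each rest on 1 such pair.

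One array with FoxO1 deleted carried an interferon response that no other array showed. The score was 3.19 in FoxO1 deleted 3 and -0.13 or less in the other 9 arrays. Leukocyte and macrophage markers were also highest in this array, at 0.66 against -0.40 to 0.18 in the others. It had the highest Actb 3' minus 5' signal (0.99) and the lowest mean correlation with its own genotype (0.956).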
